A study of Mus musculus with 8 samples.

How the data were processed

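Total RNA from sorted long-term haematopoietic stem cells (LT-HSCs) of mouse bone marrow was sequenced in 8 libraries. Per the labels, the cells were lineage-negative, CD117-positive and Sca1-positive, with high CD150 and low CD48, and they were separated by a Vwf-GFP reporter into Vwf+ and Vwf− fractions. Each fraction was taken from wild-type (WT) and from heterozygous Dnmt3a+/− mice of 10 to 12 months, which gave 4 groups of 2 libraries. Replicate 1 was male and replicate 2 female in each of the 4 groups, and each replicate was a separate pool of 3 to 4 mice. RNA was isolated with a micro-scale DNA and RNA kit, and libraries were made with a low-input kit for total RNA.

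The submitters' processing notes name Trim Galore, STAR, featureCounts and DESeq2, without versions or roles, and the mouse genome build mm10. The deposited table of raw count values holds 24421 gene symbols in 8 libraries, as whole numbers. A second deposited table holds TPM values, which sum to 1e+06 in each library and are proportional to the count divided by 1 fixed length per gene. No mitochondrially encoded gene is in either table. The notes do not state the annotation, the strand setting, the handling of reads that map to several places or whether molecular identifiers were used. Reads shared by overlapping genes and by near-identical gene families are therefore of uncertain assignment. Total counts ran from 21809278 to 39402418 per library, and 17524 to 19626 genes had a count. Coordinates are those of GENCODE M21 on GRCm38, the build also called mm10. Of the 15917 tested genes, 15279 had a single gene of that symbol in this annotation.

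Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr with a minimum count of 10, libraries were scaled by TMM (factors 0.958 to 1.06), and the quasi-likelihood F-test was applied to a model with 4 group means. All 8 libraries entered each fit, with 4 residual degrees of freedom and a common dispersion of 0.0732. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Contrasts were Vwf+ against Vwf− cells averaged over genotype and within each genotype, Dnmt3a+/− against WT cells averaged over Vwf status and within each fraction, and the interaction of genotype with Vwf status. Male and female libraries were compared with sex added to the 4 group means. The groups, comparisons, gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. Log2 changes are given with a standard error (SE), calculated back as the size of the change divided by the square root of its F statistic. Group levels are given as the mean of CPM, the counts of a gene per 1e+06 counts of a library after scaling, with the standard deviation (SD) of 2 libraries. Each p-value measures the spread between libraries, each made from a pool, and single mice were not resolved. In the model with 4 group means alone, the spread within a group is that between its male and its female pool. Differences of sex or replicate therefore count as error there.

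The replicate numbers were read as pairing libraries across groups, because the labels give the same sex to the same number in each group. The differences between replicates 1 and 2 were correlated across 15917 genes for the 6 pairs of groups, with r of 0.13, 0.2, 0.23, 0.16, 0.3 and 0.24. Without genes of the X and Y chromosomes these values were 0.1, 0.15, 0.2, 0.11, 0.27 and 0.2 over 15383 genes. Genes are not independent replicates, so these correlations carry no p-value. A fit with replicate number, and therefore sex, as a block was run beside each comparison and left 3 residual degrees of freedom. A fit with 4 blocks, each a Vwf+ and a Vwf− library of the same genotype and replicate number, left 2. The labels do not say whether such libraries came from the same mice. If they did, comparisons of genotype or sex averaged over Vwf status, and the sex by genotype interaction, rest in part on the spread between fractions of 1 pool.

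Of 33 gene lists, 31 were tested as sets with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and again with an estimated correlation. The lists covered stem cell identity, the signature of aged and platelet-biased stem cells, the megakaryocyte series, erythroid, myeloid and lymphoid priming, S phase, G2/M phase, replication-dependent histones, quiescence and cell cycle inhibitors, immediate-early response, heat shock, p53 targets, NF-κB inflammation, interferon response, TGF-β and BMP signalling, and MHC and antigen presentation. They also covered adhesion to the niche, Polycomb and HOX genes, DNA methylation machinery, imprinted genes, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, glycolysis and cholesterol synthesis. Markers of other cells were included for B cells, T and NK cells, neutrophils, monocytes and macrophages, mast cells with basophils and eosinophils, and endothelium with stroma. Mitochondrially encoded genes could not be tested, and genes linked to sex served to check the labels. The list of quiescence and cell cycle inhibitors also held Cdk6 and the D cyclin genes Ccnd1, Ccnd2 and Ccnd3, which promote the cell cycle. It shared Egr1, Nr4a1 and Btg2 with the immediate-early list. Of 822 listed genes, 797 were in the count table and 759 were tested.

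Dnmt3a and Vwf were reported in each library first. Of the genes past the adjusted threshold whose 2 groups did not overlap in CPM, or had the same sign in both strata for averaged contrasts, the 12 with the smallest p in each direction were eligible to be named, without predicted gene models, and with sex-linked genes only in the comparison of the sexes. Where fewer than 5 genes passed, the 5 with the smallest p were named as not passing. Up to 4 passing members of each list could be named in addition. Genes of the genotype contrasts that passed with the replicate block were also counted as named, outside this rule.

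Alternatives were size factors of the RLE type, no filter on counts, the Wald test of DESeq2 1.42.0, limma trend on log2(TPM + 1) for genes with a mean TPM of at least 1, a pseudocount of 0.1, fits of only the 4 libraries of a contrast, both blocks, and the omission of each library in turn, in which the library left alone in its group is assumed to vary like the other groups. A test of TPM values without a filter, list tests after RLE scaling and interactions of sex with genotype and with Vwf status were added after the data had been seen.

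The procedure was tested on simulated data made with the groups and depths of the 8 libraries. Noise was independent between libraries, and apart from the test of the sexes no gene differed consistently by sex or replicate. The size of the noise came from the real spread within the 4 groups, which includes that between male and female pools. In each test 67, 67 and 66 genes were changed by 1.5-fold, 2-fold and 4-fold. For Vwf status averaged over genotype, edgeR recovered 34.3%, 88.1% and 100% of them, and 7.5% of its 160 calls were false. The averaged genotype contrast recovered 17.9%, 85.1% and 97%, with 5.7% of 141 calls false. The contrast of Vwf status in WT cells recovered 7.5%, 47.8% and 93.9%, with 13.9% of 115 calls false. The genotype contrast in Vwf+ cells recovered 1.5%, 43.3% and 90.9%, with 8.2% of 98 calls false. The interaction recovered 0%, 7.5% and 78.8%, with 9.5% of 63 calls false, and the comparison of the sexes 31.3%, 85.1% and 98.5%, with 7.1% of 154 calls false. False shares ran from 18.7% to 26.2% for DESeq2 and from 4.6% to 16.1% for limma.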

Results

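Gene expression was measured by RNA sequencing in long-term haematopoietic stem cells (LT-HSCs) from the bone marrow of WT and Dnmt3a+/− mice. Dnmt3a encodes a de novo DNA methyltransferase, and Vwf encodes von Willebrand factor, a protein of platelets and endothelium whose reporter marks stem cells biased toward the megakaryocyte lineage. The 8 libraries formed 4 groups of 2, namely Vwf+ and Vwf− cells of each genotype, and each group held a male pool (replicate 1) and a female pool (replicate 2). Total counts of the Vwf+ Dnmt3a+/− libraries were 21809278 and 28844349 for replicates 1 and 2. The Vwf+ WT libraries had 22154192 and 23956877, the Vwf− Dnmt3a+/− libraries 39402418 and 32450785, and the Vwf− WT libraries 27891160 and 33846863. The unprocessed ribosomal precursor Rn45s took 6.08% to 11.9% of the counts. The nuclear transcript Malat1 took 0.974% to 1.97% in the 4 male libraries and 0.446% to 0.585% in the 4 female libraries.

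Vwf stood at 1220 and 1410 CPM in the Vwf+ WT libraries and at 1030 and 1200 CPM in the Vwf+ Dnmt3a+/− libraries. In the Vwf− fractions it stood at 98.9 and 115 CPM in WT and at 116 and 104 CPM in Dnmt3a+/− cells, so the sorted fractions were separated in all 8 libraries. The difference was 3.48 ± 0.14 on the log2 scale (SE), or 11.2-fold (adjusted p = 2e-06). Vwf (chromosome 6, 125546774 to 125686679) did not differ between genotypes (log2 difference −0.09 ± 0.13 SE, adjusted p = 1). Dnmt3a (chromosome 12, 3806007 to 3914443) stood at 175 and 203 CPM in Vwf+ WT, 179 and 279 CPM in Vwf+ Dnmt3a+/−, 251 and 202 CPM in Vwf− WT and 361 and 275 CPM in Vwf− Dnmt3a+/− libraries. Its transcript count was not lower in the heterozygotes, with a log2 difference of 0.38 ± 0.16 SE that did not pass (adjusted p = 1). The labels do not describe the altered allele, and counts summed over a gene do not separate alleles, so they do not check the genotype labels.

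**Figure D1:**
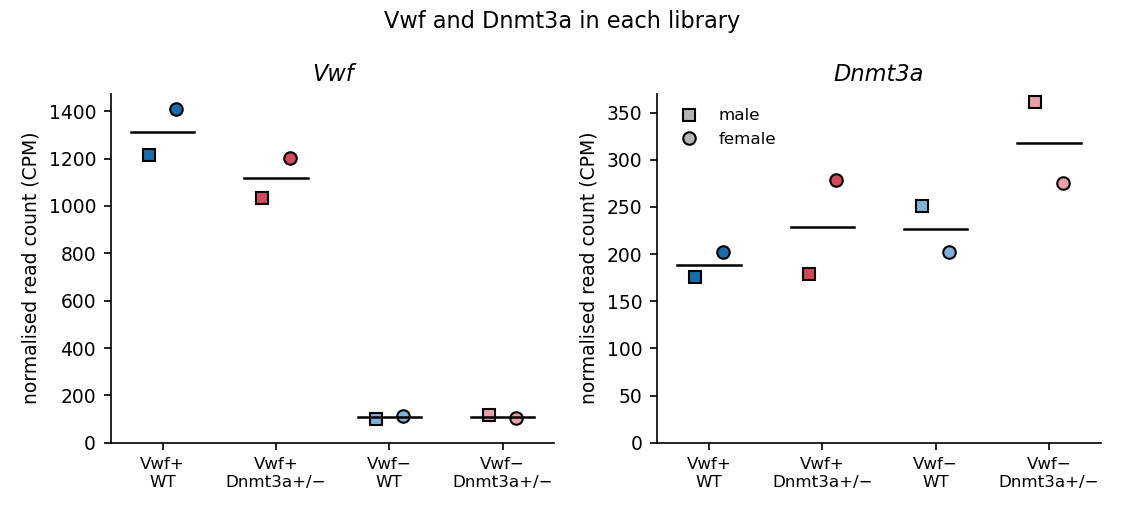
Vwf and Dnmt3a in CPM in each of the 8 libraries, with squares for male pools, circles for female pools and bars at the mean of the 2 libraries of a group. Vwf lies between 1030 and 1410 in the 4 Vwf+ libraries and between 98.9 and 116 in the 4 Vwf− libraries, and Dnmt3a lies between 175 and 361 in all 8.

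The first comparison asked how megakaryocyte-biased (Vwf+) stem cells differ from the remaining LT-HSCs. Averaged over genotype, 599 genes rose and 267 fell in Vwf+ cells. The endothelial tight-junction gene Cldn5 (chromosome 16, 18776847 to 18778262) rose 44.1-fold. In WT cells it rose 47.4-fold, from 0.682 ± 0.29 to 32.1 ± 1.5 CPM (SD, n = 2). The chaperone gene Clu (chromosome 14, 65968483 to 65981547), a marker of aged stem cells, rose 21.8-fold, and the homeobox gene Hoxb8 (chromosome 11, 96281905 to 96285315) rose 13.9-fold. The cytokine receptor gene Flt3 (chromosome 5, 147330741 to 147400489), a marker of multipotent and lymphoid-primed progenitors, fell to 5.35 ± 1.4 CPM from 40.6 ± 5.3 CPM in WT cells (SD, n = 2). Cd34 (chromosome 1, 194938819 to 194961279), a surface marker that rises as LT-HSCs differentiate, fell to 65.2 ± 1.3 CPM from 168 ± 20 CPM in WT cells.

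Among the 12 genes with the smallest p in the higher direction, the surface molecules Klrb1c, Slamf1, Neo1 and Jam2 rose by 3.58 ± 0.23, 1.83 ± 0.12, 2.97 ± 0.18 and 2.08 ± 0.14 on the log2 scale (SE). Slamf1 encodes CD150, on which the cells were sorted. The matrix gene Matn4 rose 11.8-fold, Exoc3l4 6.87-fold, Amotl2, which encodes an angiomotin-like junction protein, 5.3-fold, and the endocytic trafficking gene Ehd3 5.13-fold. In the lower direction, the nuclear receptor gene Hnf4a (chromosome 2, 163506808 to 163572910) had a log2 change of −3.40 ± 0.31 SE (adjusted p = 0.00019). The actin-binding gene Synpo2 changed by −3.41 ± 0.32, and the transporter genes Spns3 and Slc22a3 by −2.66 ± 0.20 and −1.94 ± 0.15. Mdga1, Bsn, Sh2d5, the dynein heavy chain gene Dnah8 and Fcho1 changed by −1.92, −1.83, −1.72, −1.21 and −0.85 on the log2 scale. Adjusted p-values of these genes ran from 7.8e-07 for Clu to 0.00091 for Fcho1.

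The list of genes linked to aged and platelet-biased stem cells rose as a group, with 24 of its 27 tested members higher and a median log2 change of 1.89 (adjusted p = 5.6e-31). It contains Vwf, which defines the fractions, and 25 members passed when adjusted over the list alone. Of 25 stem cell identity genes, 11 rose (16 adjusted over the list alone), including Ctnnal1 by 1.19 ± 0.11 and the homeobox gene Hoxb5 by 1.21 ± 0.15, both used as markers of LT-HSCs. Of 30 genes of the megakaryocyte series, 10 rose and 1 fell (16 and 2 adjusted over the list alone), among them the integrin gene Itgb3 by 1.36 ± 0.12 and the P-selectin gene Selp by 1.89 ± 0.25. The identity and megakaryocyte lists had adjusted p of 8.9e-10 and 9.7e-07. Endothelial and stromal markers rose as a list (median 0.81, and 0.37 on TPM, adjusted p = 1e-04), with 4 of 17 higher (5 adjusted over the list alone), including the VEGF receptor gene Kdr by 2.61 ± 0.21 and Cldn5. For these 4 lists, in the order given, adjusted p = 0.067, 0.26, 0.3 and 0.26 with an estimated correlation. The mean log2 CPM of the endothelial and stromal members, centred per gene, was uneven over the Vwf+ libraries. It was 0.6 and 0.99 in Dnmt3a+/− and 0.48 and 0.04 in WT replicates 1 and 2, and −0.54 to −0.5 in the Vwf− libraries. Whether endothelial cells in the Vwf+ fraction carried such transcripts was not tested.

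Genes of DNA replication and division were lower in Vwf+ cells. The S phase list had a median log2 change of −0.66 (adjusted p = 9.9e-11), and 4 of its 35 genes fell over all genes tested and 22 adjusted over the list alone. In the G2/M list all 35 genes had a negative change (median −0.78, adjusted p = 6.9e-09), of which 4 fell over all genes and 7 adjusted over the list alone. The replication-dependent histones, whose close sequence similarity makes the assignment of reads uncertain, had 5 of 27 lower, 23 adjusted over the list alone and a median of −0.59 (adjusted p = 1.4e-10). Dscc1, which encodes a cohesion factor at the replication fork, fell by 1.13 on the log2 scale. With replicate number as a block, 31 S phase genes, all 35 G2/M genes and 24 histone genes fell. The calls did not hold for S phase (adjusted p = 0.43), G2/M (adjusted p = 0.5) or histones (adjusted p = 0.43) with an estimated correlation.

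Immediate-early genes rose as a list (median 0.52, adjusted p = 1e-04), with 7 of 27 higher and 1 lower over all genes, and 9 and 1 adjusted over the list alone. Junb and Klf2 rose 2.23-fold and 2.82-fold, and Myc fell by 0.88 on the log2 scale. Imprinted genes rose as a list (median 0.31, and 0.18 on TPM, adjusted p = 1e-04), with 6 of 29 higher and 8 adjusted over the list alone. Dlk1 rose 4.49-fold, the neuronal growth suppressor gene Ndn 2.11-fold and Cdkn1c, which encodes the cyclin-dependent kinase inhibitor p57, 1.92-fold. Cytosolic ribosomal protein genes had a median of 0.20 (adjusted p = 2.4e-06), and 0 of 62 passed alone in edgeR, over all genes or over the list. The lymphoid priming list fell (median −0.44, adjusted p = 0.0017), with 7 of 27 lower and 1 higher, 8 and 4 adjusted over the list alone, and its lower members included Flt3, Cd34, the TNF receptor gene Cd27 and the tetraspanin gene Cd37. The MHC and antigen presentation list fell (median −0.21, adjusted p = 0.0042), with 4 of 18 lower and 7 adjusted over the list alone, among them the class II gene H2-Ab1 by −0.74 ± 0.12. For these 5 lists adjusted p = 0.41, 0.3, 0.55, 0.3 and 0.41 with an estimated correlation.

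A further 5 lists passed but lost the call when a single library was left out. The DNA methylation list had a median of −0.23 (adjusted p = 0.0073, and 0.12 without Vwf+ Dnmt3a+/− replicate 1), with 1 of 20 genes lower and 2 adjusted over the list alone. The mixed list of quiescence and cell cycle regulators had a median of 0.26 (adjusted p = 0.0085, and 0.061 without Vwf+ WT replicate 1), with 5 of 23 higher and 1 lower, 7 and 1 adjusted over the list alone. As it also lists D cyclins and immediate-early genes, its rise does not stand for quiescence alone. Polycomb and HOX genes had a median of 0.07, and 0.04 on TPM (adjusted p = 0.016, 0.087 without Vwf+ WT replicate 1 and 0.067 without Vwf− Dnmt3a+/− replicate 2), with 7 of 28 higher and 1 lower, 8 and 3 adjusted over the list alone, and Hoxb6 and the methyltransferase gene Ezh1 rose by 1.96 ± 0.35 and 0.93 ± 0.11. Mast cell, basophil and eosinophil markers had a median of −0.69, and −0.27 on TPM (adjusted p = 0.024, 0.07 on TPM, 0.16 without Vwf+ Dnmt3a+/− replicate 1 and 0.06 without Vwf− WT replicate 1), and 1 of 13, the mast cell protease gene Cpa3, fell, over all genes and adjusted over the list alone. The interferon list had a median of 0.17 (adjusted p = 0.049), with 3 of 41 higher and 1 lower, the same numbers adjusted over the list alone. Its adjusted p was 0.13 without Vwf+ Dnmt3a+/− replicate 1, 0.15 without Vwf+ WT replicate 2, 0.14 without Vwf− Dnmt3a+/− replicate 1 and 0.34 without Vwf− WT replicate 1. In the order given, adjusted p = 0.36, 0.37, 0.41, 0.39 and 0.67 with an estimated correlation.

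**Figure D2:**
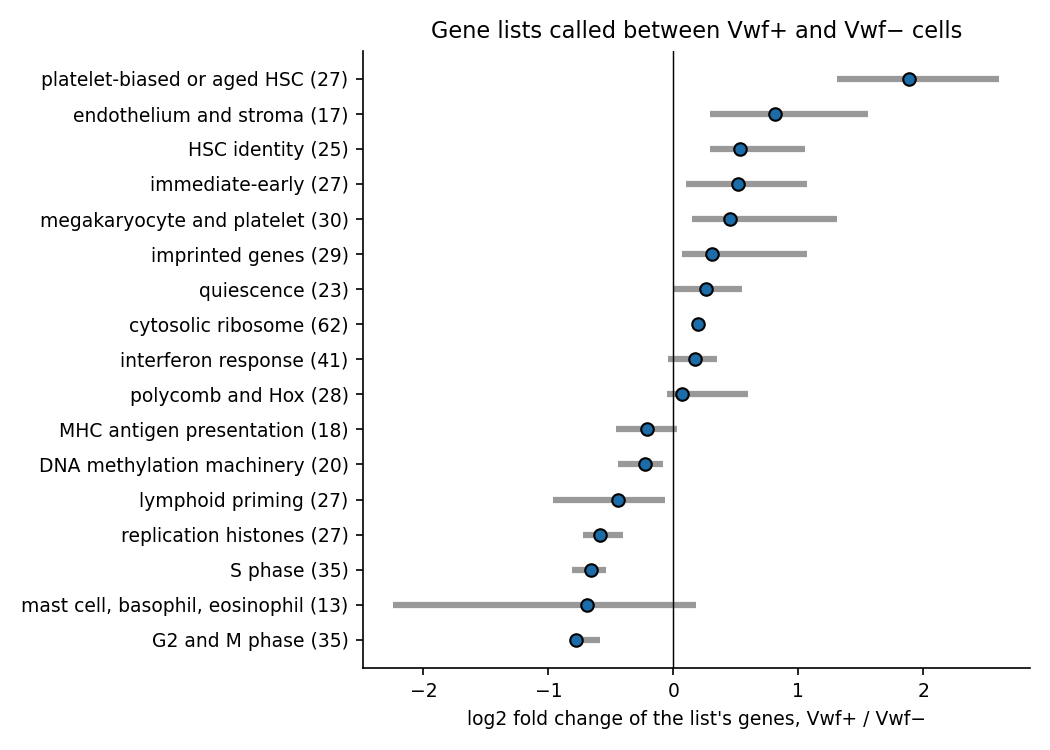
Log2 change of Vwf+ against Vwf− cells, averaged over genotype, for the 17 gene lists that passed the camera test with the preset correlation. Points mark the median of the tested members, bars run from the lower to the upper quartile, and the number of tested members stands in parentheses. Medians run from −0.78 for G2/M genes to 1.89 for the genes of aged and platelet-biased stem cells.

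Of 15917 genes tested, 866 passed in this comparison and 2742 had an unadjusted p under 0.05, against 796 expected by chance. The number was 2132 with replicate number as a block (1181 higher), 2754 with 4 blocks of a genotype and replicate number, 1353 with DESeq2 (837 higher), 475 with limma on TPM (324 higher) and 1649 without a filter. It was 472 without Vwf− WT replicate 2, 499 without Vwf+ WT replicate 2 and 1387 without Vwf− Dnmt3a+/− replicate 1. All 866 genes passed with either block and with DESeq2, and 460 with limma. No list that passed changed direction on the TPM scale.

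Vwf+ and Vwf− cells were then compared within each genotype. The changes of each genotype come from different libraries, but both tests share the variance estimates of 1 fit of all 8 libraries. A gene of low shared variance can pass more easily in both, so the overlap of independent sets is only a rough yardstick. In WT cells 235 genes rose and 79 fell, and in Dnmt3a+/− cells 142 rose and 27 fell. The higher sets had 129 genes in common where independent sets would share 2.1, and the lower sets had 24 where 0.134 would be shared. No gene passed in opposite directions, and all 314 genes of the WT test had the same sign in Dnmt3a+/− cells. Clu rose by 4.54 in WT and 4.35 in Dnmt3a+/− cells on the log2 scale, Cldn5 by 5.57 and 5.36, and Vwf by 3.62 and 3.35. Flt3 changed by −2.92 in WT and −2.32 in Dnmt3a+/− cells, and Hnf4a by −3.79 and −3.00. Across 10263 genes with a mean log2 CPM over 3, the changes of both genotypes had a correlation of 0.82, in which genes are not independent replicates. In Dnmt3a+/− cells Ramp2, which encodes a receptor activity-modifying protein, rose 22.3-fold (adjusted p = 0.0023), and the phosphatase regulator gene Ppp1r16b rose by 1.70 ± 0.17 on the log2 scale (adjusted p = 0.0022).

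**Figure D3:**
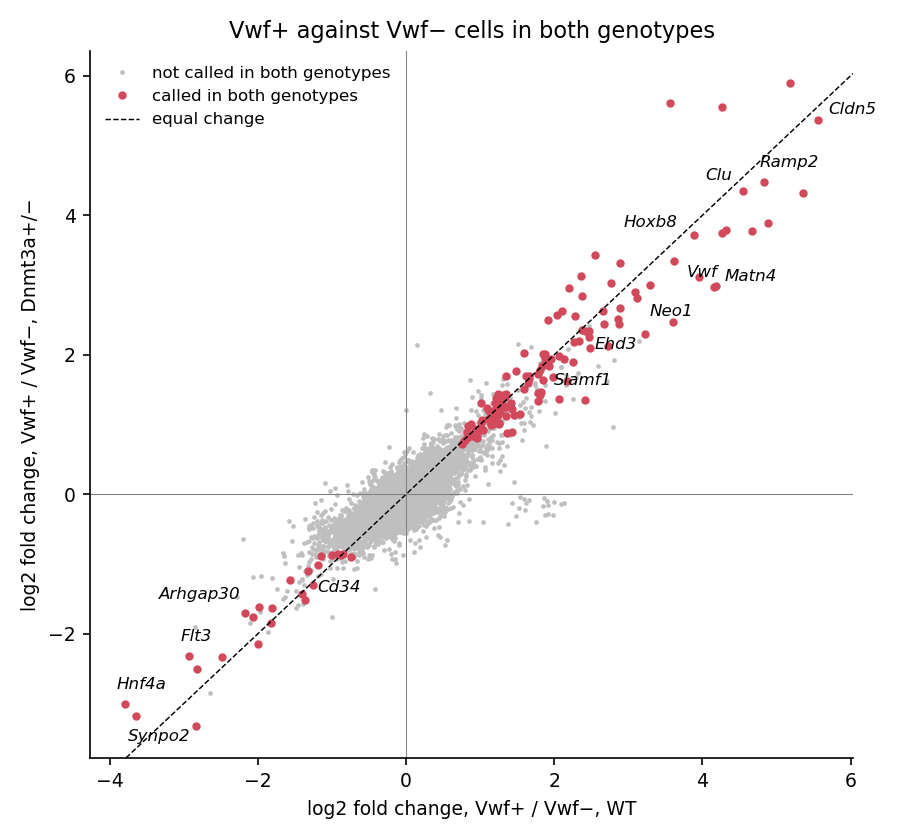
Log2 change of Vwf+ against Vwf− cells in WT (x axis) and in Dnmt3a+/− mice (y axis), with 1 point per gene and a dashed line of equal change. Red points are the 129 genes higher and 24 genes lower that passed in both genotypes, and grey points are other genes with a mean above 8 CPM.

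In both genotypes the list of aged and platelet-biased stem cells rose, with a median of 1.93 in WT and 1.84 in Dnmt3a+/− cells (adjusted p = 3.8e-31 and 8.3e-33, and 0.066 and 0.06 with an estimated correlation). It had 20 members higher in WT and 18 in Dnmt3a+/− cells, and 26 and 25 adjusted over the list alone. Stem cell identity genes rose in WT (median 0.62, 9 higher, 12 adjusted over the list alone) and in Dnmt3a+/− cells (median 0.56, 5 higher, 12 adjusted over the list alone), with adjusted p of 8.6e-09 and 6.6e-10, and 0.46 and 0.19 with an estimated correlation. The megakaryocyte list rose in Dnmt3a+/− cells (median 0.63, 4 higher, 15 adjusted over the list alone, adjusted p = 6.6e-10, and adjusted p = 0.19 with an estimated correlation). In WT cells its median was 0.29, and 0.19 on TPM (3 higher and 1 lower, 10 and 1 adjusted over the list alone, adjusted p = 0.0033), with adjusted p = 0.48 with an estimated correlation and 0.13 without Vwf+ WT replicate 1. The G2/M list fell in WT cells (median −1.04, adjusted p = 7.5e-10, and adjusted p = 0.48 with an estimated correlation), where 7 members were lower adjusted over the list alone and 0 over all genes. In Dnmt3a+/− cells its median was −0.46 (adjusted p = 0.00021, and adjusted p = 0.72 with an estimated correlation), and the adjusted p was 0.96 without Vwf+ replicate 1 and 0.94 without Vwf− replicate 2 of that genotype, where the direction turned. These omissions were fitted without sex and leave the sexes unbalanced, and with all 8 libraries the G2/M score was lower in Vwf+ than in Vwf− Dnmt3a+/− cells of both sexes (male −0.66 against −0.18, female 0.38 against 0.87). With the replicate block the adjusted p was 2.9e-10.

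The WT comparison had 1973 genes with an unadjusted p under 0.05, and the Dnmt3a+/− comparison 1435. With replicate number as a block 1329 genes passed in WT and 855 in Dnmt3a+/− cells, with DESeq2 729 and 476, with limma on TPM 81 and 79, and with the 4 libraries of a contrast alone 747 and 42. That last fit kept 313 of 314 WT calls and 42 of 169 Dnmt3a+/− calls. Chi-square per degree of freedom between the 2 libraries of a group was 31.7 and 41.7 in Vwf+ and Vwf− WT cells. In Dnmt3a+/− cells it was 68.1 and 142, and it also grows with depth. The fit of all 8 libraries shares 1 variance per gene between the genotypes. The WT number was 156 and 69 without Vwf+ WT replicates 1 and 2, 164 and 64 without Vwf− WT replicates 1 and 2, and 639 and 592 without Vwf− Dnmt3a+/− replicates 1 and 2. The Dnmt3a+/− number was 109 and 75 without Vwf+ Dnmt3a+/− replicates 1 and 2, 95 and 96 without Vwf+ WT replicates 1 and 2, and 291 without Vwf− Dnmt3a+/− replicate 1.

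The next comparison asked what heterozygous loss of Dnmt3a changed in LT-HSCs. Averaged over Vwf status, 0 genes passed in edgeR, and the following genes had the smallest p without passing. Greb1, an oestrogen-responsive gene (chromosome 12, 16670615 to 16800886), stood at 8.32 and 9.10 CPM in Vwf+ and Vwf− Dnmt3a+/− cells and at 1.16 and 0.769 CPM in WT cells (log2 difference 3.20 ± 0.41 SE, adjusted p = 0.19, and 1.3e-05 with replicate number as a block). Dnah8 (chromosome 17, 30624354 to 30877365) had a difference of 0.69 ± 0.11 (adjusted p = 0.51, block 0.0037), and the endonuclease gene Ankle1 one of 0.84 ± 0.15 (adjusted p = 0.55, block 0.014). Cfap74, which encodes a protein of the cilium axoneme (chromosome 4, 155409190 to 155466823), had a difference of 2.03 ± 0.41 (adjusted p = 0.89, block 0.00047). Its gene overlaps 5830444B04Rik on the opposite strand (155398763 to 155421704), and the strand setting of the counts is not known. Wdr90 had a difference of 0.60 ± 0.14 (adjusted p = 1, block 0.033).

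In the other direction, Slfn2, an interferon-inducible gene of the Schlafen family (chromosome 11, 83065112 to 83070678), stood at 58.1 and 23.5 CPM in Vwf+ and Vwf− Dnmt3a+/− cells and at 89.6 and 44.5 CPM in WT cells (log2 difference −0.77 ± 0.13 SE, adjusted p = 0.55, and 0.00047 with the block). The tight-junction gene Tjp1 (chromosome 7, 65296165 to 65527781) had a difference of −0.88 ± 0.17 (adjusted p = 0.86, block 0.0037). Zfp951 had a difference of −1.22 ± 0.18 (adjusted p = 0.31, block 0.0037), the adhesion gene Ncam2 one of −1.23 ± 0.21 (adjusted p = 0.52, block 0.0078) and Hoxc6 one of −1.76 ± 0.36 (adjusted p = 0.89, block 0.045). With replicate number as a block 16 genes rose and 14 fell. Chosen after their values were seen, these included the meiotic cohesin gene Rec8 (−0.98) and the MHC class II genes Cd74 (−0.63), H2-Eb1 (−0.67) and H2-Aa (−0.55 on the log2 scale) among the lower ones, and the dynein assembly gene Dnaaf3 (0.67) and the peptide transporter gene Slc15a2 (1.51) among the higher ones. The rise of Slc15a2 was larger in males, with a sex by genotype interaction of 1.42 (adjusted p = 0.0031). It stood at 39.7 and 41.4 CPM in the male Vwf+ and Vwf− Dnmt3a+/− libraries against 11.2 and 8.95 CPM in WT, and at 18.4 and 10.4 CPM in the female ones against 7.23 and 11.3 CPM. Cd74 (chromosome 18, 60803848 to 60812652) stood at 84.9 and 112 CPM in Vwf+ and Vwf− Dnmt3a+/− cells and at 131 and 172 CPM in WT cells.

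**Figure D4:**
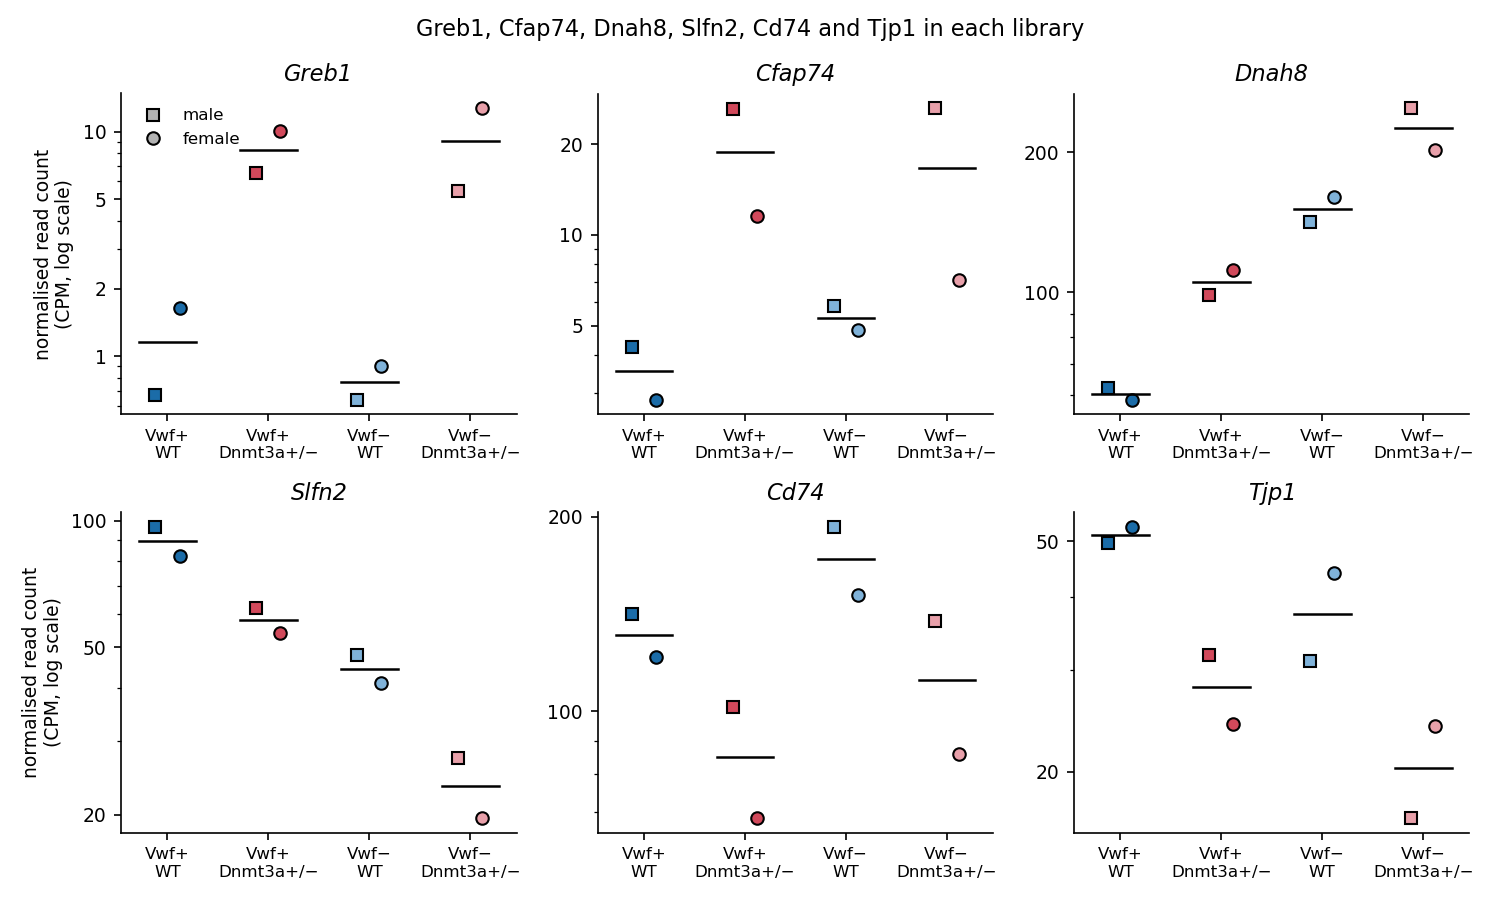
CPM, on a log scale, of Greb1, Cfap74, Dnah8, Slfn2, Cd74 and Tjp1 in the 8 libraries, with squares for male pools, circles for female pools and bars at group means. None of the 6 genes passed the averaged edgeR test with all 8 libraries, and all 6 passed it with the replicate block.

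The count of 0 genes came with 516 genes at an unadjusted p under 0.05, fewer than the 796 expected by chance. That fit has no term for sex, so the difference between the male and female pools of a group counts as error. The count became 30 with the replicate block, where 1138 genes had an unadjusted p under 0.05. It was 15 with DESeq2, 1 with limma on TPM (Mir125a, named after its value was seen) and 61 without a filter. Without Vwf− Dnmt3a+/− replicate 1 it was 2 (Greb1 and Rec8), and without Vwf− Dnmt3a+/− replicate 2 it was 3 (Greb1, Cfap74 and Slc15a2). In the simulated data, which held no consistent difference between the sexes, this contrast recovered 85.1% of 2-fold and 17.9% of 1.5-fold changes. There the spread between male and female pools entered only as independent noise of each library. The real pools differed between the sexes in part in the same direction across groups, so these shares need not hold for the count of 0.

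Among the gene lists, the MHC and antigen presentation genes had a median log2 difference of −0.20 between Dnmt3a+/− and WT cells, with 15 of 18 members negative (adjusted p = 3.9e-07). None of them passed over all genes in edgeR, 4 were lower adjusted over the list alone, and 3 passed with the block, namely Cd74, H2-Eb1 and H2-Aa. Interferon response genes had a median of −0.17, and −0.10 on TPM, with 29 of 41 negative (adjusted p = 0.00015), and ribosomal protein genes one of −0.13, and −0.07 on TPM, with 59 of 62 negative (adjusted p = 6e-07). Monocyte and macrophage markers had a median of 0.54, with 15 of 17 positive (adjusted p = 0.00016). These 4 lists passed with each library left out. The interferon score, the mean over members of log2 CPM centred per gene, was lower than in WT mainly in the female Dnmt3a+/− pools (Vwf+ −0.09 against 0.25, Vwf− −0.03 against 0.10) and nearly equal in the male pools (0.06 against 0.07, and −0.19 against −0.17). The ribosomal list passed in Vwf+ but not in Vwf− cells, as given below. With an estimated correlation the adjusted p was 0.65 for MHC, 0.65 for interferon, 0.82 for ribosomal and 0.65 for monocyte genes. In these last 3 lists 0 genes passed in edgeR, over all genes or adjusted over the list alone.

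In 9 other lists the call depended on single libraries, whose omission also unbalances the sexes in a fit without sex, and 0 member genes passed, over all genes or adjusted over the list alone. Neutrophil markers had a median of 0.81 (adjusted p = 0.014), mast cell, basophil and eosinophil markers 0.55 (0.022), G2/M genes 0.28 (0.022), histones 0.20 (0.024) and S phase genes 0.14 (0.045). Oxidative phosphorylation had a median of −0.11, and −0.06 on TPM (adjusted p = 5.5e-05), glycolysis −0.15 (0.00077), the list of aged and platelet-biased stem cells −0.10 (0.022) and cholesterol synthesis −0.09, and −0.05 on TPM (0.024). Without Vwf+ Dnmt3a+/− replicate 2, adjusted p was 0.61 for G2/M, 0.89 for S phase, 0.99 for histones and 0.19 for mast cell markers, and the direction of the first 3 turned. Without Vwf− Dnmt3a+/− replicate 2, where G2/M and S phase turned direction, it was 0.56 for G2/M, 0.33 for S phase, 0.92 for histones, 0.5 for neutrophil markers, 0.11 for mast cell markers and 0.48 for the aged and platelet-biased list. Without Vwf+ WT replicate 1 it was 0.5 for G2/M, 0.56 for S phase, 0.86 for histones (which turned direction) and 0.09 for cholesterol synthesis, and without Vwf− WT replicate 1 it was 0.91 for G2/M, 0.91 for S phase, 0.49 for histones and 0.083 for neutrophil markers. Without Vwf+ WT replicate 2 it was 0.1 for oxidative phosphorylation, 0.053 for neutrophil markers, 0.37 for mast cell markers, 0.16 for the aged and platelet-biased list and 0.067 for cholesterol synthesis. Without Vwf− Dnmt3a+/− replicate 1 it was 0.055 for oxidative phosphorylation, 0.19 for glycolysis, 0.076 for mast cell markers and 0.28 for cholesterol synthesis. Without Vwf+ Dnmt3a+/− replicate 1 it was 0.19 for neutrophil markers, 0.053 for the aged and platelet-biased list and 0.1 for cholesterol synthesis, and without Vwf− WT replicate 2 it was 0.067 for mast cell markers and 0.13 for cholesterol synthesis. With an estimated correlation the adjusted p of these lists ran from 0.65 to 0.87.

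Within Vwf+ cells 0 genes passed the genotype test in edgeR (363 at an unadjusted p under 0.05, 942 with the replicate block), 6 passed with the replicate block, 3 with DESeq2 (Greb1, Cfap74 and 5830444B04Rik), 0 with limma and 53 without a filter. With the block Cfap74 differed by 2.41 and Greb1 by 2.84 (adjusted p = 0.006 for both). Chosen after their values were seen, Rec8, Plekhg3, Zmynd15 and 5830444B04Rik also passed with the block. Within Vwf− cells 0 genes passed in edgeR (211 at an unadjusted p under 0.05, 519 with the block), 2 with the block, 2 with DESeq2 (Greb1 and 4930447C04Rik), 0 with limma and 27 without a filter. The 2 genes of the block were Greb1 (3.55 ± 0.58, adjusted p = 0.0011) and Slfn2 (−0.92 ± 0.19, adjusted p = 0.015). MHC and antigen presentation genes had a median of −0.23 in Vwf+ cells, and −0.09 on TPM, and of −0.17 in Vwf− cells (adjusted p = 1.3e-05 and 0.00024, and adjusted p = 0.72 and 0.97 with an estimated correlation), with 0 members passing over all genes or adjusted over the list alone. Ribosomal protein genes had a median of −0.25 in Vwf+ cells, and −0.11 on TPM (adjusted p = 1.3e-12, and adjusted p = 0.72 with an estimated correlation). In Vwf− cells they had a median of 0.02, and −0.01 on TPM, and did not pass (adjusted p = 0.92).

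A further 9 lists passed the genotype test in Vwf+ cells and 5 in Vwf− cells, and each lost the call when a single library was left out. In Vwf+ cells these were monocyte markers (median 0.45, adjusted p = 0.031), endothelial and stromal markers (0.54, and 0.35 on TPM, 0.023), megakaryocyte genes (0.20, and 0.32 on TPM, 0.031), G2/M (0.49, 0.00021) and S phase genes (0.23, 0.0056). Lower there were oxidative phosphorylation (−0.21, and −0.07 on TPM, adjusted p = 6.7e-07), interferon genes (−0.16, and −0.02 on TPM, 0.0005), glycolysis (−0.19, and −0.06 on TPM, 0.0057) and the aged and platelet-biased list (−0.20, and −0.06 on TPM, 0.0056). On TPM the monocyte and endothelial lists did not pass (adjusted p = 0.051 and 0.1). Without Vwf+ Dnmt3a+/− replicate 2 the monocyte and endothelial lists had adjusted p of 0.62 and 0.42, and G2/M, S phase and megakaryocyte genes turned direction. In Vwf− cells the lists were monocyte markers (median 0.66, and 0.42 on TPM, adjusted p = 0.00068, and 0.24 without Vwf− WT replicate 2), neutrophil markers (1.35, and 0.84 on TPM, 0.03, and 0.95 without Vwf− Dnmt3a+/− replicate 2), histones (0.21, 0.015), glycolysis (−0.14, 0.03) and interferon genes (−0.05, and −0.08 on TPM, 0.03). Histones turned direction without Vwf− Dnmt3a+/− replicate 2 and glycolysis without replicate 1. In all 14 cases 0 members passed, over all genes or adjusted over the list alone. With an estimated correlation the adjusted p ran from 0.72 to 0.79 in Vwf+ cells and was 0.97 in Vwf− cells.

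The interaction of genotype with Vwf status asked whether loss of a Dnmt3a allele acted differently in the megakaryocyte-biased cells. In edgeR 0 genes passed (159 at an unadjusted p under 0.05, 365 with the replicate block), and 0 passed with the block, DESeq2 or limma and 24 without a filter. The smallest p-values included Tmem100 (log2 interaction 3.95) and Grap2 (3.14) in the positive direction and Kcnb2 (−4.88) and the BMP decoy receptor gene Bambi (−1.21) in the negative one, each with adjusted p = 1. Dnmt3a and Vwf had interactions of −0.21 ± 0.33 and −0.27 ± 0.26 (SE). Ribosomal protein genes had a median interaction of −0.27, and −0.11 on TPM (adjusted p = 2.3e-08, and 0.13 without Vwf− WT replicate 2), and genes of the megakaryocyte series one of 0.28 (adjusted p = 0.0026, and 0.38 without Vwf+ Dnmt3a+/− replicate 2). A further 4 lists passed and each lost the call in 4 of 8 omissions of a library, namely G2/M (0.49, adjusted p = 0.0024), S phase (0.23, and 0.42 on TPM, 0.049), oxidative phosphorylation (−0.19, and −0.03 on TPM, 0.0024) and immediate-early genes (−0.36, and −0.09 on TPM, 0.031). G2/M and S phase turned direction in 2 of these omissions and immediate-early genes in 1. With an estimated correlation the adjusted p was 0.88 for each of the 6 lists. In the simulated data, which held no consistent difference between the sexes, this contrast recovered 7.5% of 2-fold and 78.8% of 4-fold changes. On the TPM scale the median of all genes was shifted by −0.133 for Vwf status in WT cells, by 0.126 for genotype in Vwf+ cells and by 0.165 for the interaction, and the list medians that changed sign belonged to lists that had not passed, among them the interaction of MHC genes (−0.06, and 0.13 on TPM).

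Male and female pools were compared across the 4 groups, first to check the labels. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d stood between 42.9 and 93.6 CPM in the male libraries and at 0.287 CPM or less in the female libraries, and Xist (X chromosome, 103460366 to 103483254) stood at 2.02 to 4.94 CPM in males and 1230 to 1780 CPM in females, as labelled. Genes of cell division were lower and immediate-early genes higher in the male pools. The mitotic regulators Plk1, Ccnb2, Hmmr, Cdc20 and Ccnb1 fell by 1.17, 1.08, 1.04, 0.93 and 0.90 in males on the log2 scale. Fosb, Dusp1, Jun and Rhob rose by 1.62 ± 0.15, 1.17 ± 0.11, 0.95 ± 0.11 and 0.84 ± 0.10 (SE). The transcriptional repressor gene Gfi1 (chromosome 5, 107716657 to 107726036), which restrains proliferation of stem cells, rose 3.68-fold, and Pkhd1l1, Mamdc2 and Mapk12 rose by 1.36, 0.93 and 1.16. Higher in females were the matricellular gene Thbs1 (−3.80 ± 0.36), the light chain gene Myl10 (−3.22 ± 0.13), Creb5 (−3.78 ± 0.23), the desmosome gene Dsp (−1.91 ± 0.25), the X-linked gene Eif2s3x (−0.91 ± 0.11) and Cux1 (−0.86 ± 0.11).

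In the G2/M list 34 of 35 genes were lower in males, over all genes and adjusted over the list alone (median −0.87, adjusted p = 2.2e-20). The S phase list had 26 of 35 lower and 28 adjusted over the list alone (median −0.57, adjusted p = 2.4e-14), including the helicase gene Mcm2 and the ribonucleotide reductase gene Rrm2. Of the histones 19 of 27 were lower and 25 adjusted over the list alone (median −0.45, adjusted p = 8.5e-14). Immediate-early genes had 12 of 27 higher and 2 lower, 16 and 2 adjusted over the list alone (median 0.66, adjusted p = 6.8e-05). Each of these 4 lists had adjusted p = 0.65 with an estimated correlation. The share of Malat1, a nuclear transcript, was also higher in the male library of each of the 4 groups, at 1.31% against 0.578%, 0.974% against 0.558%, 1.97% against 0.446% and 1% against 0.585%. The share of Rn45s was lower in the male library of each group, at 7.31% against 11.9%, 8.96% against 9.19%, 6.08% against 9.83% and 8.07% against 8.24%. Glycolysis genes had a median of −0.23 (5 of 19 lower and 1 higher, 8 and 1 adjusted over the list alone, adjusted p = 0.027), with 0.16 and 0.14 without Vwf− Dnmt3a+/− replicates 1 and 2. Erythroid genes had a median of −0.30 (3 of 19 lower, 4 adjusted over the list alone, adjusted p = 0.04), with 0.086 and 0.093 without Vwf− Dnmt3a+/− replicates 1 and 2 and 0.22 and 0.21 without Vwf− WT replicates 1 and 2. With an estimated correlation the adjusted p of these 2 lists was 0.84 and 0.74.

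**Figure D5:**
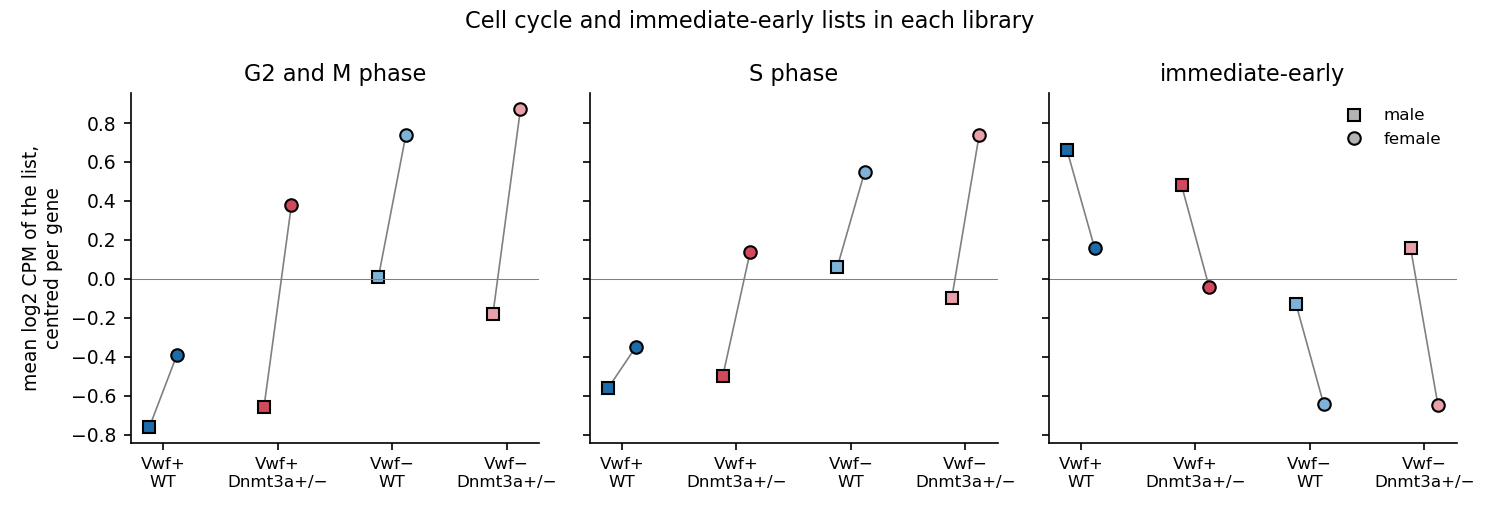
List scores of G2/M, S phase and immediate-early genes in each library, where a score is the mean over members of log2 CPM centred per gene and lines join the male and female pools of a group. The female pool has the higher G2/M score and the lower immediate-early score in all 4 groups, and G2/M scores run from −0.76 to 0.87.

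In this comparison 783 genes were higher and 894 lower in males (1677, with 3990 at an unadjusted p under 0.05). Limma on TPM gave 453, of which 69.5% were higher in males against 46.7% in edgeR. The number was 1099 and 987 without Vwf+ Dnmt3a+/− replicates 1 and 2, 2922 and 2891 without Vwf+ WT replicates 1 and 2, and 765 and 713 without Vwf− Dnmt3a+/− replicates 1 and 2. Sex and replicate number coincide in all 4 groups, so a difference between the sexes and any other difference between the first and second replicates cannot be told apart.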

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

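Both tests of an interaction with sex were chosen after the results had been seen, and so was the list of eosinophil markers, whose test was written before the values it measures. The difference between Dnmt3a+/− and WT cells differed between the sexes for 61 genes, by a test of the sex by genotype interaction in edgeR (34 positive and 27 negative, 1378 at an unadjusted p under 0.05). Each combination of sex and genotype holds 2 libraries, a Vwf+ and a Vwf− one, and if these came from the same mice, which the labels do not say, the test rests on the spread between fractions of 1 pool. The named genes below were chosen after their values were seen. The eosinophil granule genes Prg2 and Epx stood at 34.9 and 15 CPM in the female Vwf+ Dnmt3a+/− library and at 18 and 12.5 CPM in the female Vwf− Dnmt3a+/− library, against at most 2.63 and 2.53 CPM in the other 6. Fn1 and F13a1, genes of monocytes and platelets, were also highest in those 2 libraries (F13a1 38.9 and 15.9 CPM). In the same females the interferon-inducible GTPase genes Tgtp1, Tgtp2, Iigp1 and Gbp4 were lower than in WT females, with interactions of 0.99, 0.95, 0.93 and 1.37 on the log2 scale. Meg3, an imprinted noncoding RNA, had an interaction of 2.04 ± 0.27 (SE, adjusted p = 2.6e-08), and the mitotic genes Top2a and Tpx2 interactions of −0.81 and −0.90. The number of genes was 97 and 103 without Vwf+ Dnmt3a+/− replicates 1 and 2, 39 without Vwf+ WT replicate 1, and 174 and 171 without Vwf− WT replicates 1 and 2.

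The difference between Vwf+ and Vwf− cells differed between the sexes for 6 genes, by a test of the sex by Vwf interaction in edgeR (404 at an unadjusted p under 0.05). These were the platelet factor gene Pf4 (−1.87), the immunoglobulin joining chain gene Jchain (−2.44), the neutrophil granule gene Ngp (4.74) and the small noncoding RNAs Snora74a (−2.37), Scarna6 (−1.38) and Mir6516 (−2.05 on the log2 scale). Snora74a stood at 480 CPM in the female Vwf+ WT library and at 50.3 to 126 CPM in the other 7. The number of genes was 71 and 67 without Vwf+ Dnmt3a+/− replicates 1 and 2, 20 and 19 without Vwf+ WT replicates 1 and 2, 33 and 31 without Vwf− Dnmt3a+/− replicates 1 and 2, and 11 and 22 without Vwf− WT replicates 1 and 2.

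For the eosinophil granule transcripts of the female Dnmt3a+/− libraries, neutrophils or granulocyte progenitors among the sorted cells were tested with the neutrophil and myeloid priming lists, of which 1 of 35 detected members (Ly6c2) was highest in both libraries (exact binomial p = 0.72). A count at the level of chance was set beforehand as the bound against this source, but such a count excludes nothing, so this source stays open, and the granule genes Mpo and Elane go both ways, with sex by genotype interactions of −2.44 and −1.93 but neither highest in both libraries (Mpo 105 and 24.8 CPM, Elane 13.6 and 3.83 CPM, against up to 78.1 and 15.6 CPM in the other 6). Of 7 detected eosinophil markers apart from Prg2 and Epx, 2 (Prg3 and Il5ra) were highest in both libraries, where chance gives 3.57% for each marker (exact binomial p = 0.024). This p takes markers read in the same libraries as independent. Il5ra stood at 0.434 and 0.511 CPM there against 0.33 CPM in Vwf− WT replicate 2. Ear1, Ear2, Siglecf, Ccr3 and Alox15 were not highest in both. Eosinophils or their RNA in the sorted cells may be a source, but these low counts do not settle it. Prg3 and Il5ra reached only 1.98 and 0.511 CPM, and the lineage-negative gate is meant to remove such cells. An effect of genotype limited to females stays open, untested.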

How the results depend on the processing

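The TPM test without a filter, RLE scaling of the lists and the sex interactions were added after the data had been seen, and for each change below the cause was not tested unless the setting itself has fewer genes or libraries. Between Vwf+ and Vwf− cells, averaged and then in WT and Dnmt3a+/− cells, the number of genes (866, 314 and 169) was 1649, 1059 and 633 without a filter, 1353, 729 and 476 with DESeq2, 475, 81 and 79 with limma on TPM, 2132, 1329 and 855 with replicate number as a block and 2754, 1872 and 1257 with 4 blocks. With only the 4 libraries of the contrast it was 747 in WT and 42 in Dnmt3a+/− cells. With 1 library left out it ran from 472 to 1387, from 64 to 639 and from 75 to 291. Between genotypes in edgeR, averaged and then in Vwf+ and Vwf− cells, the number (0 each, with 516, 363 and 211 at an unadjusted p under 0.05) was 61, 53 and 27 without a filter, 15, 3 and 2 with DESeq2, 30, 6 and 2 with the block, and 1, 0 and 0 with limma. With 1 library left out it ran from 0 to 3 for the averaged genotype test and stayed at 0 in both fractions. The genotype by Vwf interaction (0 in edgeR, 159 at an unadjusted p under 0.05, and 0 with DESeq2 or limma) gave 24 without a filter. Between the sexes (1677) limma on TPM gave 453, and with 1 library left out the number ran from 713 to 2922. It ran from 39 to 174 for the sex by genotype interaction (61) and from 11 to 71 for the sex by Vwf interaction (6). RLE size factors kept each of the 8 numbers within 1.5-fold. A pseudocount of 0.1 moved 2 of 8 limma numbers, and no filter on TPM moved 5. Of 89 list calls in 8 contrasts, 0 were kept with an estimated correlation, and 77 to 95 lists were called with 1 library left out. The block ended the megakaryocyte and monocyte calls of the genotype test in Vwf+ cells (adjusted p = 0.063 and 0.064) and made 3 lists pass in Vwf− cells (cholesterol 0.021, immediate-early 0.038, Polycomb and HOX 0.032). It also made 38 named-gene results pass. These are the genotype results that passed with the block, all counted as named for that reason, so this number was fixed in advance. The block changed no other call of a list or named gene. Lists turned direction when 1 library was left out, with these adjusted p, in fits without sex that an omission leaves unbalanced between the sexes. The G2/M list in the Vwf comparison of Dnmt3a+/− cells (range 2.1e-12 to 0.96) had 0.96 without Vwf+ Dnmt3a+/− replicate 1 and 0.94 without Vwf− Dnmt3a+/− replicate 2. In the averaged genotype test, without Vwf+ and then Vwf− Dnmt3a+/− replicate 2, G2/M had 0.61 and 0.56 (range 1.1e-06 to 0.91) and S phase 0.89 and 0.33 (range 1.6e-06 to 0.91), and histones had 0.99 without Vwf+ Dnmt3a+/− replicate 2 and 0.86 without Vwf+ WT replicate 1 (range 4.1e-06 to 0.99). In Vwf+ cells, without Dnmt3a+/− replicate 2, G2/M had 0.62 (from 3.1e-10), S phase 0.67 (from 2.5e-06) and megakaryocyte genes 0.93 (from 3.3e-05). In Vwf− cells glycolysis had 0.85 without Dnmt3a+/− replicate 1 (from 0.00013) and histones 0.81 without Dnmt3a+/− replicate 2 (from 0.00025). In the genotype by Vwf interaction, without Vwf+ Dnmt3a+/− replicate 2 and then Vwf− Dnmt3a+/− replicate 1, G2/M had 0.85 and 0.99 (from 9.9e-09) and S phase 0.77 and 0.35 (range 4.6e-08 to 0.9), and immediate-early genes had 0.99 without the latter (from 6.2e-05). Changes of Dnmt3a and Vwf that had not passed turned sign on the log2 scale without passing. Dnmt3a between genotypes in Vwf+ cells was −0.08 without Dnmt3a+/− replicate 2 (range −0.08 to 0.56), and Vwf in Vwf− cells was −0.05 without Dnmt3a+/− replicate 1 and −0.06 without WT replicate 1 (range −0.06 to 0.15). Dnmt3a in the interaction was 0.08 without Vwf+ and 0.02 without Vwf− Dnmt3a+/− replicate 1 (range −0.57 to 0.08), and between the sexes 0.17 without either Vwf+ Dnmt3a+/− replicate and 0.02 and 0.03 without Vwf+ WT replicates 1 and 2 (range −0.19 to 0.17). Of the other comparisons with 1 library left out, 582 list results kept their side of the threshold and 112 lost it, and 2437 named-gene results kept it, 373 lost it and 5 passed it newly. With each library thinned to 21809278 counts the sexes differed in 1660 genes against 1677 at full depth. In the simulated data, made at full depth, the averaged genotype test recovered 17.9% of 1.5-fold changes.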

Other observations

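The tests of committed progenitors, of a day or library round and of the region around Dnmt3a were chosen after the results had been seen. Single members of the myeloid priming, erythroid and adhesion lists moved between Vwf+ and Vwf− cells without these lists passing. Among 21 myeloid priming genes, the neutrophil proteinase gene Prtn3 rose by 0.88 ± 0.11 and the cytotoxic granule gene Nkg7 changed by −1.69 ± 0.27 on the log2 scale (SE), and the list had a median of 0.08 (adjusted p = 0.73). In the erythroid list Tmem56 rose by 1.84 ± 0.30, and the list median was −0.32 (adjusted p = 0.58). Of 29 adhesion genes 5 rose and 3 fell (9 and 4 adjusted over the list alone), with Alcam and Itgb3 higher by 1.25 and 1.36 and Cd34 lower, and the list did not pass (median 0.09, adjusted p = 0.26). Markers of neutrophils (median −0.53, adjusted p = 0.26), B cells (0.22, 0.66), T and NK cells (0.14, 0.58) and monocytes (0.07, 0.66) did not pass, nor did p53 targets (0.14, 0.055), glycolysis (0.10, 0.12), heat shock (0.12, 0.12), NF-κB (0.12, 0.49), TGF-β and BMP (0.04, 0.49), cholesterol synthesis (−0.06, 0.66) or oxidative phosphorylation (0.02, 0.84). The medians of monocyte, T and NK cell, NF-κB, TGF-β and oxidative phosphorylation genes turned negative on TPM, and the camera test of monocyte genes pointed lower against its positive median.

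Male pools had higher transcripts of several regulators of stem cells. Procr, a surface marker of LT-HSCs, rose by 0.88 ± 0.11 and Hoxb4 by 0.82 ± 0.13, and the Polycomb gene Cbx7 rose by 0.65 ± 0.11 on the log2 scale (SE). The lineage factors Gata1 and Cebpa were higher in female pools, with male against female changes of −1.34 ± 0.21 and −1.55 ± 0.26. The methyltransferase genes Dnmt1 and Ezh2 and the methylation cofactor gene Uhrf1, which are also transcribed with DNA replication, were higher in female pools (−0.73, −0.46 and −0.91), and Dnmt3a did not differ (−0.03, adjusted p = 0.9). The DNA methylation list had a median of −0.07, and −0.01 on TPM, and did not pass between the sexes. The Polycomb and HOX list did not pass either, nor did stem cell identity genes as a list (median 0.16, adjusted p = 0.071).

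The lower mitotic and higher immediate-early transcripts of the male pools were weighed against depth, committed cells and handling. With each library thinned to 21809278 counts the G2/M median was −0.86, against −0.87 at full depth. The number of lower genes was 33 against 34, so these calls did not rest on the unequal totals. Thinning keeps the share of each gene on average, so the median could hardly move and does not decide on depth otherwise. More committed progenitors among the female cells stay open, since the 4 lists of myeloid, erythroid, lymphoid and megakaryocyte genes all had negative medians, with −0.05 as the largest, but only the erythroid list passed (adjusted p = 0.04). A day, operator or library round that differed between replicates 1 and 2 cannot be told apart from sex, because both coincide in 4 of 4 groups, and a biological difference between the sexes was not tested apart from it.

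Greb1, the gene with the largest averaged genotype difference among those named, lies 12.8 Mb from Dnmt3a on chromosome 12, so alleles of the flanking region carried along with the altered allele could raise or lower transcripts there. Within 25 Mb of Dnmt3a 8 of 80 tested genes had an unadjusted p under 0.05 with the replicate block, 10% against 7.15% elsewhere (one-sided Fisher's exact p = 0.21). The 8 include Greb1, which prompted the test, so the 10% is raised by the choice of region. The few genes keep this explanation open. Cfap74, Dnah8 and Dnaaf3, which belong to axoneme families, led to a test of whether such genes are higher as a class in Dnmt3a+/− cells. Without the 3 genes that had passed, 21 of 46 members were positive, with a median of −0.03 (camera p = 0.3, and p = 0.35 with an estimated correlation). A median at or below 0 was set beforehand as the bound against a change of the class, but over members that go both ways and without the genes that passed it decides nothing, so this stays open.

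The 8 libraries were also split into 2 groups of 4 in all 35 ways and tested without other terms. The Vwf split gave 1115 genes and the highest other split 18, so 1 of 35 splits gave as many. These splits do not keep the pairing of the replicates and differ in their balance of the sexes. The share is therefore no exact test, and it does not exclude chance. Split by genotype, the libraries gave 0 genes, and 35 of 35 splits gave at least as many, so this count says nothing about chance. The highest other was 1115, the Vwf split, which is a structure of the samples. Split by sex they gave 18 genes, and 2 of 35 splits gave as many. The other of these was again the Vwf split with 1115, so this count does not exclude chance and does not speak for it. Splits that exchange genotypes within the 4 pairs of the same Vwf status and sex gave 21 genes for the real split, 1 of 8 with as many, and 1 gene for the highest other. Splits that take 1 library of each group gave 1677 genes for sex, 1 of 8 with as many, and 0 for the highest other in edgeR. In both cases 8 splits cannot give a share under 0.05.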
